A study of Mus musculus with 26 samples.

How the data were processed

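Liver RNA of 26 mouse samples was sequenced, with RNA taken by Trizol and libraries made with a TruSeq kit, per the labels' protocols. The labels name HISAT and Bowtie2 without versions and the genome build mm10, and the tool that counted reads is not given in the sources used here. The deposited tables hold 1 line per gene with an expected count, an estimate of reads per gene that need not be whole, per the file headers. They also hold FPKM, the authors' values of fragments scaled by gene length and library size, per the file headers, whose exact formula is not given in the sources used here. Genes are listed only where they had reads: the smallest listed count was 0.02, the smallest listed FPKM 0.01, and a gene missing from a library was taken as 0. Of the listed counts 20.1 to 21.8% were not whole, and counts were rounded for the tests.

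Gene IDs were matched to the reference annotation (names from GRCm38.p6, the same assembly as mm10). Of 19638 genes listed in at least 1 library, 19573 matched by Entrez gene ID, 11 by RefSeq accession and 54 had no symbol. Coordinates are those of that annotation and count from 1. The 5 genes with the most counts took 11.3 to 21.6% of a library. Counting error alone limits precision at a few counts, so genes with all libraries of a group at 0 are given as a bound against 3 counts over the group, which covers counting error only.

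Groups followed the labels. The 17 young livers were fitted together (13617 genes) and the 9 older tissues together (13187 genes), after edgeR's filterByExpr and TMM scaling, with the 2-sided quasi-likelihood F-test of edgeR 4.0.16 and Benjamini-Hochberg adjustment at 0.05. The comparisons, gene lists, rule for named genes and alternatives were fixed before the data were examined, except for those on Y-linked transcripts, camera with 1 library left out and the comparisons of 21d with 7d and with 50d. The labels do not say that replicates are separate animals. Replicates differed in Y-linked transcripts within tumor and within adjacent tissue and in beta-globin haplotype within 0d and within 7d, so each of these groups holds libraries of at least 2 animals. Replicates of every group differed by more than counting error (chi-square per degree of freedom 7.67 to 292.21 over pairs), and in the other groups that spread may be technical. Equal replicate numbers did not mark pairs: the deviations of equal numbers correlated at between -0.22 and 0.26.

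The named genes were the 6 largest rises and the 6 largest falls past the threshold per comparison, with a mean of at least 5 CPM in the higher group and no overlap between groups. To these came up to 4 members of each list with the smallest adjusted p. Named in every case were Hdac3, Fah, Alb, Afp, H19, Igf2, Gpc3, Mki67, Ccnd1, Myc, Cyp7a1, Glul, Epcam, Krt19 and Sox9, and the text gives a part of these genes, with 1 item not reported here. Lists covered cell cycle, fetal and tumor markers, biliary and progenitor markers, bile acids, lipogenesis, cholesterol synthesis, fatty acid oxidation, glucose, urea cycle and amino acids, xenobiotic enzymes, plasma proteins, Wnt and pericentral genes, p53 targets, interferon response, acute phase, hypoxia and glycolysis, and matrix. Further lists covered macrophages, lymphocytes, neutrophils, sinusoidal endothelium, erythroid cells, exocrine pancreas, male-biased and female-biased liver genes, immediate early genes, clock genes, and corepressors with HDACs. Of 460 genes on 29 lists 4 were in no table, and the list of sex chromosome genes was used for values only. The other 28 lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and at an estimated one, and with fry, adjusted over the lists of a comparison.

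Alternatives were DESeq2 1.42.0, edgeR with DESeq2's size factors or library totals, no filter or a stricter one, all samples or only the groups compared, limma voom with quality weights and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1). A stricter adjusted p of 0.01, a 2-fold minimum, a replicate block and leaving out each library in turn were also run. After the data were seen, the presence of Y-linked transcripts was added as a covariate, and the libraries holding them were left out. Camera was then also run without each library in turn. Genes changed by known amounts were recovered in simulated counts, with 30 to 40% of 2-fold and 78 to 87% of 4-fold changes in the comparisons of young livers. In the older tissues 1% of 2-fold and 15 to 35% of 4-fold changes were recovered, and 0 to 12.2% of the calls were false. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.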

Results

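RNA-seq counts were obtained for 26 mouse liver libraries in 8 groups. Young livers, aged 2 to 3 months, comprised wild type (WT, 3 libraries) and livers labelled Alb-Cre:Hdac3-/-, a hepatocyte-directed deletion of a histone deacetylase. The latter were taken 0 days (0d, 3 libraries), 7 days (7d, 4), 21 days (21d, 4) and 50 days (50d, 3) after successive PH (sPH), where PH is the usual abbreviation of partial hepatectomy. The labels do not say whether WT livers had sPH, or whether 0 days means before the first or at the end of the successive operations. What 0d against WT and the later days against 0d compare is open in that respect. Older tissue comprised Hdac3-/- tumors (3 libraries, 10 months), adjacent tissue without tumor (3, 10 months) and tumors of Fah-/- recipient mice (3, 12 months). Library totals ran from 8602526 to 11094627 counts, and 15369 to 16373 genes were listed per library. Numbers in parentheses after a gene are log2 fold changes ± SE, or mean TMM-scaled CPM ± SD where CPM is named, with the first-named group of the comparison first. Where leaving out 1 library moved a named fold change by over 1.5 times, the log2 fold change without it follows. Tests are edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Counts over a list alone are adjusted over its members only. Gene lists were tested with camera, whose direction (up or down) and adjusted p are given where that p lay below 0.05 at a preset correlation. The adjusted p if the correlation is estimated follows and, where leaving out 1 library ended the call at the preset correlation, the adjusted p without it.

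Hdac3 (gene ID 15183, chromosome 18, 37936971 to 37955015, GRCm38), the targeted gene, was not lower in the libraries labelled Hdac3-/-. Its level was 46.6 ± 3.48 against 34.5 ± 2.51 CPM in 0d and WT livers, a rise (adjusted p = 0.0316) that did not pass without WT replicate 2 or 3 or without any 1 of the 0d libraries. In tumors and adjacent tissue it was 60.9 ± 5.47 against 58.1 ± 5.83 CPM (adjusted p = 0.875). Counts over a whole gene do not separate its exons, so a deletion that leaves a transcript was not checked by them, and the genotype rests on the labels. Fah (gene ID 14085, chromosome 7, 84585159 to 84605942), the tyrosine-degrading enzyme missing by label from the recipient mice, stood at 372 ± 105 against 356 ± 96.7 CPM in recipient and Hdac3-/- tumors.

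Sex-linked transcripts divided the young livers. Xist, the X-inactivation RNA, ranged from 195 to 308 CPM of the unscaled library in WT and from 212 to 235 in 0d. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to at most 0.31 there. In all 11 libraries of 7d, 21d and 50d these genes summed to between 37.5 and 81.4, and Xist was at most 4.29. Tumor replicate 3 and adjacent replicate 2 also held Y-linked transcripts. Each comparison of a later day with 0d therefore also set livers with against livers without Y-linked transcripts, while 0d against WT and 50d against 7d did not. Hbb-bs and Hbb-bt, the beta-globin genes of 1 haplotype, made up 99.6 to 100% of adult beta-globin counts in WT and 52.7 to 99.6% in 0d. They made up 0 to 2.8% in 7d, 21d and 50d except for 48.1% in 7d replicate 4, so the groups differed in haplotype as well. The labels give C57BL/6 as the strain of all 26 samples, which a difference in haplotype does not match, so the strain background of these groups is in doubt.

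**Figure D1:**
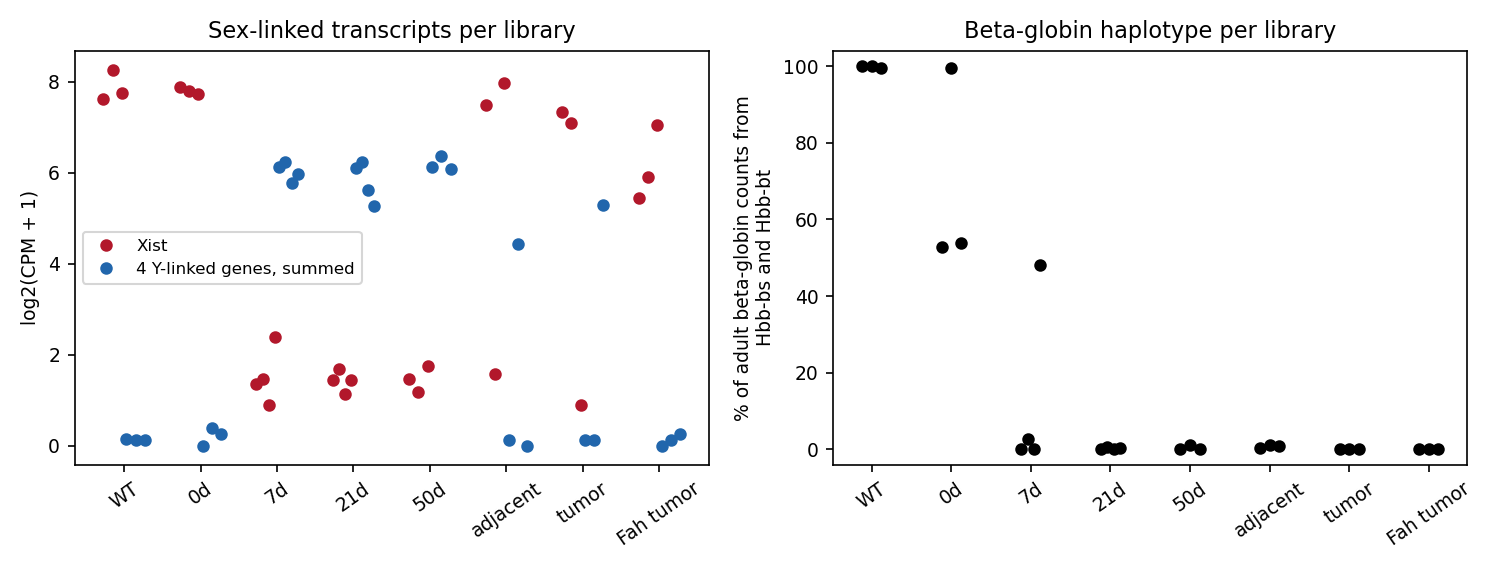
Xist and the sum of the Y-linked genes as log2(CPM + 1) (left) and the percentage of adult beta-globin counts from Hbb-bs and Hbb-bt (right), with 1 point per library in 8 groups. All 11 libraries of 7d, 21d and 50d held Y-linked transcripts, and those of WT and 0d did not.

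Livers labelled Hdac3-/- at 0 days held less of many hepatocyte products and more markers of bile duct, progenitor and fetal liver cells than WT. Bile duct markers rose, among them Krt19 (23.8 ± 6.38 against 1.08 ± 0.406 CPM), a keratin of duct cells, and Epcam (17.1 ± 4.91 against 1.53 ± 1.38 CPM, log2 fold change 3.49, 4.50 without WT replicate 1), an adhesion molecule. Fetal and tumor markers rose as well, with Afp (6.74 ± 2.65 against 1.13 ± 0.236 CPM), alpha-fetoprotein, Scd2 (6.13 ± 0.82), a desaturase, and the growth factor Igf2 (4.38 ± 1.16). Hepatocyte products fell, from Alb (31082 ± 5447 against 121141 ± 4619 CPM), albumin (gene ID 11657, chromosome 5, 90460870 to 90476602), to Vtn (-2.79 ± 0.38), vitronectin, and F9 (-2.59 ± 0.40), a clotting factor. So did the pericentral enzyme glutamine synthetase, Glul (135 ± 24.2 against 1161 ± 198 CPM), with gene ID 14645 at 153899929 to 153909723 of chromosome 1.

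Of the biliary and progenitor markers 13 of 15 rose, 1 fell and 1 did not pass (13 higher and 1 lower over the list alone, camera up at adjusted p = 1.69e-07, 0.345 if estimated). Spp1 (3.75 ± 0.45), osteopontin, was among the rises. Of the fetal and tumor markers 11 of 15 rose and 4 did not pass (13 higher over the list alone, camera up at adjusted p = 2.94e-06, 0.345 if estimated). Of the secreted plasma proteins 19 of 23 fell and 4 did not pass (19 lower over the list alone, camera down at adjusted p = 4.41e-07, 0.345 if estimated). Of the urea cycle and amino acid genes 16 of 17 fell and 1 did not pass (17 lower over the list alone, camera down at adjusted p = 7.64e-09, 0.345 if estimated). Hpd (-3.18 ± 0.34), an enzyme of tyrosine breakdown, and Hal (-3.50 ± 0.47), histidase, fell. Of the Wnt and pericentral genes 12 of 15 fell and 3 did not pass (13 lower over the list alone, camera down at adjusted p = 4.41e-07, 0.345 if estimated). Lect2 (-3.37 ± 0.28) and Notum (-2.28 ± 0.32), which inactivates Wnt proteins, fell beside Glul. Of the bile acid genes 3 of 20 rose, 14 fell and 3 did not pass (3 higher and 14 lower over the list alone, camera down at adjusted p = 0.00361, 0.548 if estimated). The uptake carrier Slc10a1 (-3.37 ± 0.50) and the sterol hydroxylase Cyp8b1 (-6.05 ± 1.04) fell, while the export pump Abcc4 (7.51 ± 1.39, 8.13 without WT replicate 2) rose. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 64.8 ± 15.2 against 52.3 ± 45.9 CPM (adjusted p = 0.685).

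Some lipid and sugar genes rose and others fell. Of the cholesterol synthesis genes 12 of 23 fell and 11 did not pass (12 lower over the list alone, camera down at adjusted p = 0.000425, 0.548 if estimated). Pmvk (-2.49 ± 0.31) and Dhcr7 (-1.91 ± 0.33) fell. Of the lipogenesis and lipid droplet genes 10 of 23 rose, 5 fell and 8 did not pass (11 higher and 5 lower over the list alone). Me1 (2.04 ± 0.42), malic enzyme, and Elovl6 (2.00 ± 0.40), a fatty acid elongase, rose, while Plin4 (-2.98 ± 0.51), a droplet coat protein, fell. Of the fatty acid oxidation genes 6 of 20 rose, 3 fell and 11 did not pass (7 higher and 4 lower over the list alone). The peroxisomal enzymes Ehhadh (2.95 ± 0.66) and Acaa1b (2.17 ± 0.48) rose. Of the glucose metabolism genes 1 of 12 rose, 7 fell and 4 did not pass (1 higher and 8 lower over the list alone, camera down at adjusted p = 0.018, 0.525 if estimated). Pck1 (-2.13 ± 0.48), a step of glucose synthesis, fell. Of the hypoxia and glycolysis genes 8 of 15 rose, 1 fell and 6 did not pass (8 higher and 1 lower over the list alone, camera up at adjusted p = 0.0253, 0.345 if estimated, 0.078 without WT replicate 2). Hk2 (3.86 ± 0.55) and Pkm (2.43 ± 0.44), enzymes of glycolysis, rose. Of the xenobiotic enzymes 7 of 22 rose, 8 fell and 7 did not pass (7 higher and 8 lower over the list alone). The glutathione transferase Gsta1 (7.98 ± 1.21, 8.58 without WT replicate 2) rose.

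Of the p53 targets 8 of 16 rose, 1 fell and 7 did not pass (10 higher and 1 lower over the list alone, camera up at adjusted p = 0.000585, 0.345 if estimated). Btg2 (2.62 ± 0.31) and Plk2 (2.32 ± 0.37) rose. Of the cell cycle genes 5 of 32 rose, 2 fell and 25 did not pass (5 higher and 2 lower over the list alone, camera up at adjusted p = 0.0144, 0.613 if estimated, 0.101 without WT replicate 3). Mki67 (1.87 ± 0.61), the proliferation marker, and Mcm2 (1.72 ± 0.42) rose and Tk1 (-2.08 ± 0.19) fell. Myc (3.24 ± 0.53, 3.87 without WT replicate 2), a growth regulator, rose, and Ccnd1 stood at 59.9 ± 10.3 against 69.3 ± 36.7 CPM (adjusted p = 0.658). Of the acute phase genes 8 of 15 fell and 7 did not pass (9 lower over the list alone, camera down at adjusted p = 0.00939, 0.574 if estimated). Of the interferon response genes 9 of 17 fell and 8 did not pass (9 lower over the list alone, camera down at adjusted p = 0.0279, 0.606 if estimated, 0.177 without WT replicate 2). Of the matrix and stellate cell genes 11 of 19 rose and 8 did not pass (14 higher over the list alone, camera up at adjusted p = 0.000146, 0.548 if estimated). Of the macrophage markers 8 of 16 rose, 2 fell and 6 did not pass (10 higher and 2 lower over the list alone, camera up at adjusted p = 0.00179, 0.548 if estimated). Gpnmb (6.97 ± 0.83, 8.17 without WT replicate 2) and Trem2 (4.88 ± 0.82) rose and Timd4 (-1.95 ± 0.34), a marker of resident macrophages, fell. Of the neutrophil markers 0 of 9 passed with edgeR (5 at an unadjusted p under 0.05, 6 by DESeq2, 0 by limma voom, camera up at adjusted p = 0.0253, 0.606 if estimated, 0.0682 without WT replicate 1). Of the lymphocyte markers 2 of 13 rose, 2 fell and 9 did not pass (2 higher and 2 lower over the list alone). Of the sinusoidal endothelium markers 1 of 11 rose and 10 did not pass (3 at an unadjusted p under 0.05 and 0 over the list alone with edgeR, 2 by DESeq2, 5 by limma voom). Of the female-biased liver genes 8 of 11 fell and 3 did not pass (2 higher and 8 lower over the list alone, camera down at adjusted p = 0.000406, 0.345 if estimated). Of the male-biased liver genes 4 of 11 rose, 2 fell and 5 did not pass (4 higher and 2 lower over the list alone). Gstp1 (3.01 ± 0.27) rose although neither group held Y-linked transcripts.

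From WT to 0d 5082 of 13617 genes changed, 2490 higher and 2592 lower. Rpl34-ps1 was at least 438-fold higher, Serpinb9e at least 387-fold higher and Ptgds at least 51.2-fold lower, against 3 counts over the group at 0. Hbb-b1, Hbb-b2, Rpl34-ps1 and Serpinb9e have near-identical copies and stay uncertain. Scaled by library totals, the median log2 fold change of all genes was 0.30 and 69.7% of the changed genes were higher, against 49.0%. Fatty acid oxidation and erythroid genes, whose medians lie within that shift, get no direction. Of the genes named here as changed other than Hdac3, Mki67 did not pass without WT replicate 1 or 3 or 0d replicate 1 or 3. The signs of median, mean and camera differed for lymphocyte markers and erythroid genes.

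At 7 days livers labelled Hdac3-/- held more of many hepatocyte, pericentral and acute phase transcripts than at 0 days and less of several fetal, lipogenic and matrix transcripts, with Y-linked transcripts in the later libraries only. Acute phase proteins rose, with Orm1 (3810.5 ± 2326 against 438 ± 36.7 CPM), orosomucoid, Apcs (3.71 ± 0.56), serum amyloid P, and Saa1 (7.01 ± 1.11, 5.85 without 7d replicate 3), serum amyloid A. Pericentral Glul (813 ± 495 against 135 ± 24.2 CPM), Slc1a2 (4.70 ± 0.82, 4.03 without 7d replicate 2), a glutamate carrier, and Lect2 (2.56 ± 0.26) rose, as did the bile acid enzymes Cyp8b1 (5.43 ± 1.00, 4.40 without 7d replicate 2) and Cyp7a1 (2.06 ± 0.54). Fetal markers fell, with Afp (1.60 ± 0.111 against 6.74 ± 2.65 CPM), Scd2 (-3.49 ± 0.64, -4.18 without 7d replicate 3), Igf2 (-4.27 ± 1.02) and Gpc3 (-2.98 ± 0.73, -3.91 without 7d replicate 3), a surface proteoglycan. Alb stood at 39859 ± 29452 against 31082 ± 5447 CPM (adjusted p = 0.566) and Mki67 at 16.2 ± 12.9 against 15.9 ± 1.16 CPM (adjusted p = 0.979).

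Among the acute phase genes 15 of 15 rose (15 higher over the list alone, camera up at adjusted p = 4.46e-11, 0.341 if estimated). Among the neutrophil markers 9 of 9 rose (9 higher over the list alone, camera up at adjusted p = 0.000494, 0.341 if estimated). S100a9 (3.56 ± 0.86, 2.02 without 7d replicate 3), of neutrophil granules, and Ltf (3.40 ± 0.80, 1.92 without 7d replicate 3), lactoferrin, rose. Without 7d replicate 3, 7 of 9 neutrophil markers rose, and 6 of 9 without 0d replicate 1 and 7 of 9 without 0d replicate 3. Among the secreted plasma proteins 15 of 23 rose and 8 did not pass (16 higher over the list alone, camera up at adjusted p = 2.16e-06, 0.341 if estimated). Vtn (2.43 ± 0.36) and F9 (2.19 ± 0.38) rose. Among the urea cycle and amino acid genes 11 of 17 rose and 6 did not pass (13 higher over the list alone, camera up at adjusted p = 2.16e-06, 0.341 if estimated). Sds (2.53 ± 0.36) and Hpd (2.18 ± 0.32) rose. Among the Wnt and pericentral genes 11 of 15 rose and 4 did not pass (13 higher over the list alone, camera up at adjusted p = 2.02e-06, 0.341 if estimated). Among the bile acid genes 12 of 20 rose, 2 fell and 6 did not pass (13 higher and 2 lower over the list alone, camera up at adjusted p = 0.027, 0.576 if estimated, 0.0857 without 7d replicate 1, 0.0964 without 7d replicate 2). Among the fetal and tumor markers 8 of 15 fell and 7 did not pass (9 lower over the list alone, camera down at adjusted p = 5.37e-05, 0.341 if estimated). Among the biliary and progenitor markers 6 of 15 fell and 9 did not pass (6 lower over the list alone, camera down at adjusted p = 0.000708, 0.341 if estimated). Sox4 (-2.53 ± 0.53, -3.25 without 7d replicate 4) and Prom1 (-2.19 ± 0.59, -3.13 without 7d replicate 3) fell. Among the lipogenesis and lipid droplet genes 1 of 23 rose, 12 fell and 10 did not pass (2 higher and 12 lower over the list alone, camera down at adjusted p = 0.000228, 0.341 if estimated). Me1 (-2.75 ± 0.39) and Acly (-1.48 ± 0.29), citrate lyase, fell. Among the fatty acid oxidation genes 9 of 20 fell and 11 did not pass (10 lower over the list alone, camera down at adjusted p = 5.66e-05, 0.341 if estimated). Pdk4 (-2.31 ± 0.32) and Cyp4a14 (-2.67 ± 0.37) fell. Among the cholesterol synthesis genes 6 of 23 rose and 17 did not pass (6 higher over the list alone, camera up at adjusted p = 0.0223, 0.629 if estimated, 0.0964 without 7d replicate 2). Among the matrix and stellate cell genes 9 of 19 fell and 10 did not pass (13 lower over the list alone, camera down at adjusted p = 2.02e-06, 0.341 if estimated). Acta2 (-2.94 ± 0.56), smooth muscle actin, and Lox (-2.86 ± 0.51), a collagen cross-linking enzyme, fell. Among the sinusoidal endothelium markers 3 of 11 fell and 8 did not pass (3 lower over the list alone, camera down at adjusted p = 0.0124, 0.532 if estimated, 0.0509 without 7d replicate 1, 0.057 without 7d replicate 2). Among the interferon response genes 6 of 17 rose and 11 did not pass (8 higher and 1 lower over the list alone, camera up at adjusted p = 0.00331, 0.428 if estimated). Among the macrophage markers 2 of 16 rose, 1 fell and 13 did not pass (2 higher and 1 lower over the list alone). Timd4 (2.51 ± 0.33) and Marco (246 ± 230.1 against 9.95 ± 3.53 CPM, log2 fold change 4.63, 3.73 without 7d replicate 3) rose and Gpnmb (-2.99 ± 0.54) fell. Among the p53 targets 1 of 16 rose, 7 fell and 8 did not pass (1 higher and 7 lower over the list alone, camera down at adjusted p = 0.00424, 0.341 if estimated). Among the cell cycle genes 2 of 32 rose and 30 did not pass (2 higher over the list alone). Among the male-biased liver genes 10 of 11 rose and 1 did not pass (10 higher over the list alone, camera up at adjusted p = 0.000829, 0.341 if estimated). Among the female-biased liver genes 4 of 11 fell and 7 did not pass (5 lower over the list alone, camera down at adjusted p = 0.00424, 0.341 if estimated). Among the erythroid genes 1 of 6 rose, 3 fell and 2 did not pass (1 higher and 4 lower over the list alone, camera down at adjusted p = 0.0237, 0.341 if estimated, 0.0652 without 7d replicate 3). That list holds globins that differ between haplotypes.

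From 0d to 7d 3626 genes changed, 2004 higher and 1622 lower. Without 0d replicate 1 the count was 1752, without 0d replicate 2 it was 2412 and without 0d replicate 3 it was 2364. Of the genes named here as changed, Cyp7a1 and Prom1 did not pass without 0d replicate 1, nor Gpc3 without 0d replicate 2. Scaled by library totals, the median log2 fold change of all genes was -0.13 and 38.0% of the changed genes were higher, against 55.3%. Glucose metabolism genes and xenobiotic enzymes get no direction for that reason. Uty, a Y-linked gene, was at least 63.8-fold higher. Mup1, Mup10, Mup14 and Serpina4-ps1, among the largest rises, belong to families with near-identical copies. The signs of median, mean and camera differed for xenobiotic enzymes and clock genes.

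At 21 days livers labelled Hdac3-/- again held more of many acute phase, pericentral and plasma protein transcripts than at 0 days and less of some bile duct and fetal markers, with Y-linked transcripts in the later libraries only. Acute phase genes rose, with Apcs (650.0 ± 211 against 59.5 ± 0.778 CPM), Crp (2.83 ± 0.48), C-reactive protein, and Saa1 (5.53 ± 1.03). The plasma proteins Vtn (2.59 ± 0.36) and Apoa1 (2.06 ± 0.36), of high-density lipoprotein, rose as well. Pericentral Glul (779 ± 368 against 135 ± 24.2 CPM), Slc13a3 (2.45 ± 0.28) and Notum (1.61 ± 0.31) rose, with Cyp8b1 (6.50 ± 1.05) and the bile acid carrier Slc10a1 (2.38 ± 0.47). Fetal Afp (1.91 ± 0.522 against 6.74 ± 2.65 CPM), Scd2 (-3.89 ± 0.65, -4.71 without 21d replicate 3) and Gpc3 (-4.95 ± 0.87, -5.66 without 21d replicate 3) fell, and so did the bile duct markers Krt19 (-1.39 ± 0.51), Epcam (-1.55 ± 0.54), Sox9 (-0.98 ± 0.30) and Cd24a (-2.12 ± 0.46).

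Of the acute phase genes 12 of 15 rose and 3 did not pass (13 higher over the list alone, camera up at adjusted p = 2.65e-06, 0.337 if estimated). Of the secreted plasma proteins 18 of 23 rose and 5 did not pass (19 higher over the list alone, camera up at adjusted p = 5.48e-06, 0.337 if estimated). Of the urea cycle and amino acid genes 10 of 17 rose and 7 did not pass (11 higher over the list alone, camera up at adjusted p = 5.48e-06, 0.337 if estimated). Of the Wnt and pericentral genes 12 of 15 rose and 3 did not pass (12 higher over the list alone, camera up at adjusted p = 5.48e-06, 0.337 if estimated). Of the bile acid genes 10 of 20 rose, 2 fell and 8 did not pass (11 higher and 2 lower over the list alone, camera up at adjusted p = 0.023, 0.554 if estimated). Of the cholesterol synthesis genes 8 of 23 rose and 15 did not pass (8 higher over the list alone, camera up at adjusted p = 0.00213, 0.554 if estimated). Dhcr7 (1.84 ± 0.32) and Pmvk (1.72 ± 0.29) rose. Of the fetal and tumor markers 7 of 15 fell and 8 did not pass (8 lower over the list alone, camera down at adjusted p = 0.000207, 0.337 if estimated). Of the biliary and progenitor markers 8 of 15 fell and 7 did not pass (8 lower over the list alone, camera down at adjusted p = 0.00167, 0.4 if estimated). Of the lipogenesis and lipid droplet genes 12 of 23 fell and 11 did not pass (1 higher and 12 lower over the list alone, camera down at adjusted p = 0.000218, 0.337 if estimated). Scd1 (-2.27 ± 0.46, -2.91 without 21d replicate 3), stearoyl-CoA desaturase, and Fabp4 (-2.57 ± 0.49), a fatty acid carrier, fell. Of the fatty acid oxidation genes 9 of 20 fell and 11 did not pass (1 higher and 10 lower over the list alone, camera down at adjusted p = 0.000334, 0.345 if estimated). Of the matrix and stellate cell genes 10 of 19 fell and 9 did not pass (11 lower over the list alone, camera down at adjusted p = 2.65e-06, 0.345 if estimated). Pdgfrb (-1.62 ± 0.32), a growth factor receptor, fell. Of the sinusoidal endothelium markers 1 of 11 fell and 10 did not pass (7 lower over the list alone, camera down at adjusted p = 0.00839, 0.554 if estimated). Of the interferon response genes 6 of 17 rose and 11 did not pass (6 higher over the list alone, camera up at adjusted p = 0.0229, 0.554 if estimated, 0.138 without 21d replicate 3). Of the hypoxia and glycolysis genes 4 of 15 fell and 11 did not pass (4 lower over the list alone, camera down at adjusted p = 0.015, 0.337 if estimated). Of the p53 targets 1 of 16 rose, 5 fell and 10 did not pass (1 higher and 7 lower over the list alone, camera down at adjusted p = 0.00216, 0.345 if estimated). Myc (-1.29 ± 0.44) fell. Of the macrophage markers 2 of 16 rose, 1 fell and 13 did not pass (2 higher and 1 lower over the list alone). Of the erythroid genes 1 of 6 rose, 3 fell and 2 did not pass (1 higher and 3 lower over the list alone, camera down at adjusted p = 0.0293, 0.337 if estimated). Alas2 (2.87 ± 0.81), an enzyme of heme synthesis, rose, and the list holds globins that differ between haplotypes. Of the male-biased liver genes 8 of 11 rose and 3 did not pass (9 higher over the list alone, camera up at adjusted p = 0.000218, 0.337 if estimated). Of the female-biased liver genes 5 of 11 fell and 6 did not pass (5 lower over the list alone, camera down at adjusted p = 0.00373, 0.337 if estimated).

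From 0d to 21d 4303 genes changed, 2394 higher and 1909 lower, and 2484 changed without 0d replicate 1. Of the genes named here as changed, Krt19, Epcam, Sox9, Myc and Alas2 did not pass without 0d replicate 1 or 3. Krt19, Epcam, Sox9 and Myc did not pass without 21d replicate 1 either, nor Krt19, Epcam and Myc without 21d replicate 2 or 4, nor Krt19 and Myc without 0d replicate 2. Scaled by library totals, the median log2 fold change of all genes was -0.21 and 35.1% of the changed genes were higher, against 55.6%. Xenobiotic enzymes, clock genes and neutrophil markers get no direction for that reason. Nat8 was at least 69.4-fold higher and Pcdhac2 at least 167-fold lower. The signs of median, mean and camera differed for xenobiotic enzymes and clock genes.

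At 50 days most cholesterol synthesis and acute phase genes stood above 0d and most fatty acid oxidation genes below it. Only the later libraries held Y-linked transcripts. The sterol enzymes Dhcr7 (232 ± 7.14 against 40.7 ± 2.800 CPM), Mvk (2.75 ± 0.39) and Pmvk (2.26 ± 0.31) rose. The oxidation enzymes Cyp4a14 (61.1 ± 14.2 against 566 ± 49.1 CPM), a fatty acid hydroxylase, Hadha (-0.98 ± 0.17) and Hadhb (-1.20 ± 0.18), of the mitochondrial trifunctional protein, fell. Orm1 (3.58 ± 0.48), Apcs (4.26 ± 0.58), Vtn (2.82 ± 0.38) and Glul (2.61 ± 0.51) rose, and Afp (-1.84 ± 0.30), Igf2 (-5.22 ± 1.23), Scd2 (-3.36 ± 0.71) and Myc (-1.86 ± 0.49) fell. Clock genes moved, with a rise of Arntl (1.82 ± 0.34) and falls of Per3 (-3.31 ± 0.51) and Tef (-2.32 ± 0.37).

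Among the cholesterol synthesis genes 17 of 23 rose and 6 did not pass (17 higher over the list alone, camera up at adjusted p = 4.73e-09, 0.316 if estimated). Among the fatty acid oxidation genes 16 of 20 fell and 4 did not pass (18 lower over the list alone, camera down at adjusted p = 2.32e-09, 0.316 if estimated). Among the acute phase genes 14 of 15 rose and 1 did not pass (15 higher over the list alone, camera up at adjusted p = 1.69e-12, 0.316 if estimated). Among the secreted plasma proteins 15 of 23 rose and 8 did not pass (15 higher over the list alone, camera up at adjusted p = 4.73e-07, 0.316 if estimated). Among the Wnt and pericentral genes 12 of 15 rose and 3 did not pass (12 higher and 1 lower over the list alone, camera up at adjusted p = 4.70e-06, 0.316 if estimated). Among the urea cycle and amino acid genes 9 of 17 rose and 8 did not pass (9 higher over the list alone, camera up at adjusted p = 0.000317, 0.414 if estimated). Among the bile acid genes 9 of 20 rose, 4 fell and 7 did not pass (11 higher and 5 lower over the list alone). Nr0b2 (2.25 ± 0.48), a corepressor induced by bile acids, rose and Abcc3 (-1.78 ± 0.23), an export pump, fell. Among the lipogenesis and lipid droplet genes 11 of 23 fell and 12 did not pass (1 higher and 13 lower over the list alone, camera down at adjusted p = 4.76e-05, 0.316 if estimated). Plin2 (-2.01 ± 0.47), a droplet coat protein, and Me1 (-2.88 ± 0.44) fell. Among the fetal and tumor markers 6 of 15 fell and 9 did not pass (6 lower over the list alone, camera down at adjusted p = 0.000317, 0.394 if estimated). Among the biliary and progenitor markers 3 of 15 fell and 12 did not pass (3 lower over the list alone). Among the clock genes 3 of 15 rose, 8 fell and 4 did not pass (4 higher and 9 lower over the list alone, camera down at adjusted p = 0.0374, 0.394 if estimated). Among the interferon response genes 8 of 17 rose, 1 fell and 8 did not pass (9 higher and 1 lower over the list alone, camera up at adjusted p = 0.00816, 0.466 if estimated). Irf7 (1.84 ± 0.29) and Psmb8 (1.72 ± 0.30) rose. Among the macrophage markers 4 of 16 rose, 2 fell and 10 did not pass (4 higher and 2 lower over the list alone, camera up at adjusted p = 0.0398, 0.626 if estimated, 0.0509 without 0d replicate 2, 0.0565 without 0d replicate 3, 0.0695 without 50d replicate 1). Marco (319 ± 46.0 against 9.95 ± 3.53 CPM) and Timd4 (2.90 ± 0.34) rose and Gpnmb (-4.12 ± 0.65) fell. Among the matrix and stellate cell genes 5 of 19 fell and 14 did not pass (7 lower over the list alone, camera down at adjusted p = 0.000114, 0.438 if estimated). Among the sinusoidal endothelium markers 1 of 11 fell and 10 did not pass (6 at an unadjusted p under 0.05 and 0 over the list alone with edgeR, 4 by DESeq2, 7 by limma voom, camera down at adjusted p = 0.0358, 0.597 if estimated, 0.111 without 0d replicate 3, 0.084 without 50d replicate 2). Among the hypoxia and glycolysis genes 1 of 15 rose, 5 fell and 9 did not pass (1 higher and 7 lower over the list alone, camera down at adjusted p = 0.0172, 0.316 if estimated). Among the p53 targets 2 of 16 rose, 6 fell and 8 did not pass (2 higher and 8 lower over the list alone, camera down at adjusted p = 0.0398, 0.466 if estimated, 0.0608 without 0d replicate 1, 0.0728 without 0d replicate 3, 0.104 without 50d replicate 2). Among the male-biased liver genes 5 of 11 rose and 6 did not pass (6 higher over the list alone, camera up at adjusted p = 0.00291, 0.394 if estimated). Among the female-biased liver genes 4 of 11 fell and 7 did not pass (4 lower over the list alone, camera down at adjusted p = 0.00526, 0.316 if estimated).

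From 0d to 50d 3507 genes changed, 1955 higher and 1552 lower. The count was 2026 without 0d replicate 1, 2082 without 50d replicate 1 and 1995 without 50d replicate 3. Of the genes named here as changed, Myc did not pass without 50d replicate 1. Scaled by library totals, the median log2 fold change of all genes was -0.17 and 39.2% of the changed genes were higher, against 55.7%. Cell cycle and glucose metabolism genes get no direction for that reason. Nat8 was at least 88.4-fold higher and Hbb-bt, which differs between haplotypes, at least 147-fold lower. The signs of median, mean and camera differed for glucose metabolism genes, xenobiotic enzymes and immediate early genes.

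**Figure D2:**
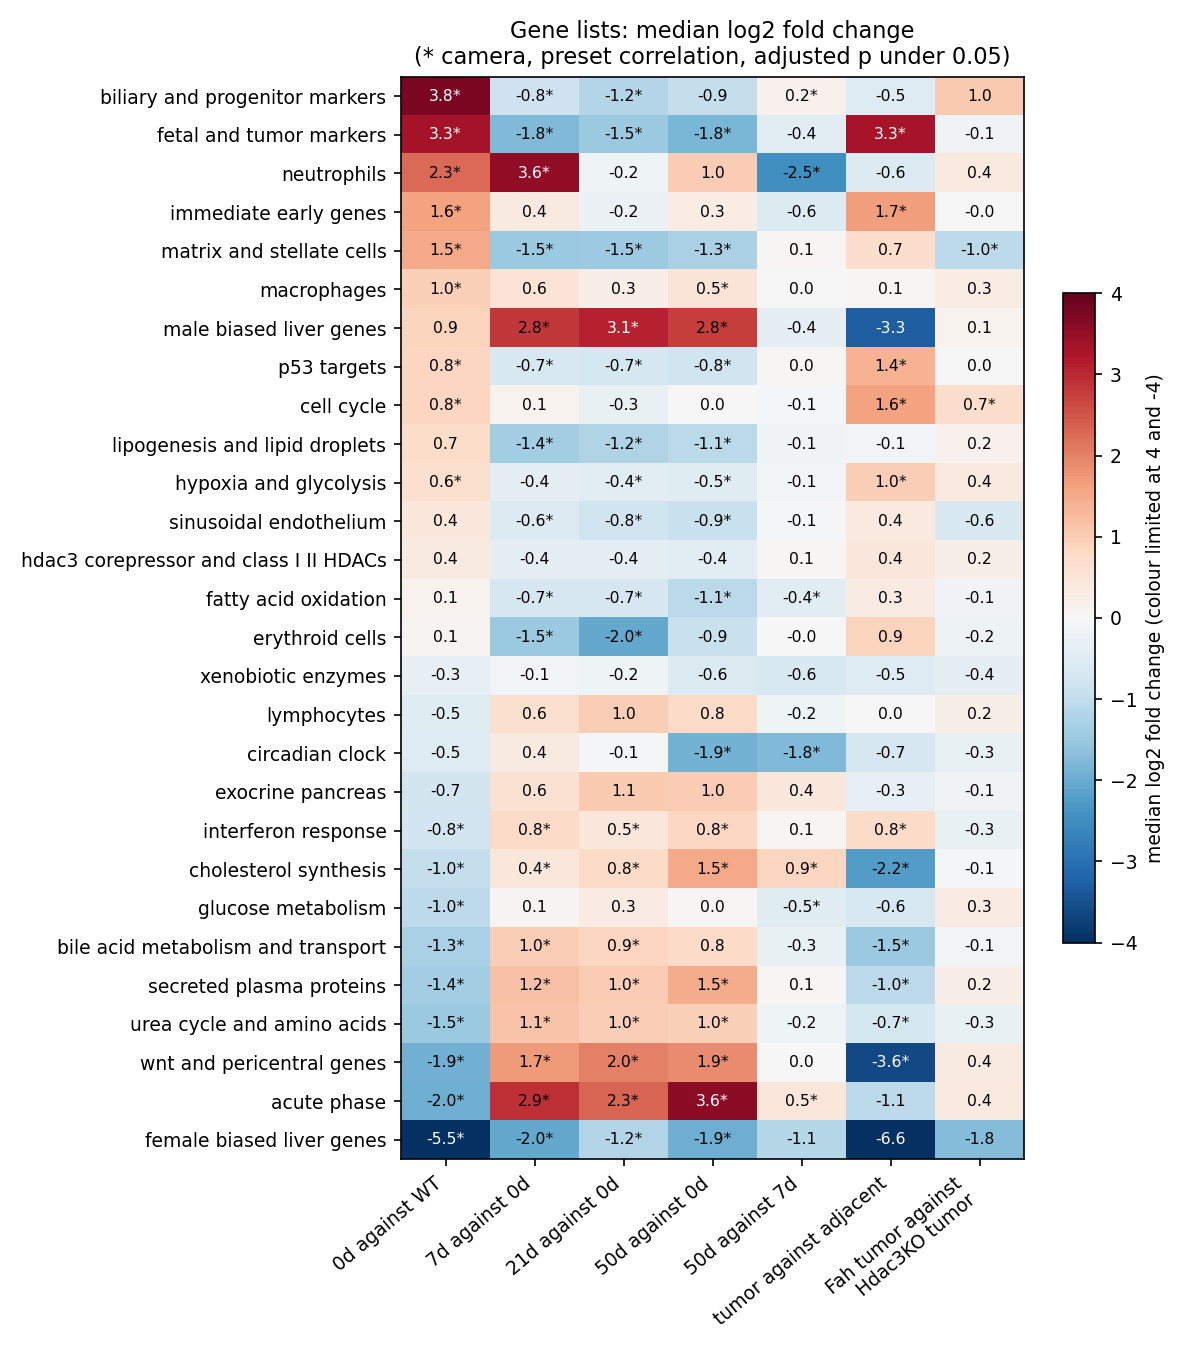
Median log2 fold change of 28 gene lists (vertical axis) in 7 comparisons (horizontal axis), printed in each cell, with an asterisk where camera's adjusted p lay below 0.05 at a preset correlation and fitted values for genes at 0 in a group. Pericentral and plasma protein lists lay below 0 in 0d against WT and above 0 in 7d, 21d and 50d against 0d.

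Between 7 and 50 days, with Y-linked transcripts in all 7 libraries, clock genes were among the few changes. Arntl (27.0 ± 2.46 against 3.36 ± 0.788 CPM), a core activator, Npas2 (4.48 ± 0.76) and Nfil3 (1.46 ± 0.21) rose. Per3 (-3.55 ± 0.50), Dbp (-4.23 ± 0.81), Tef (-2.73 ± 0.37), Ciart (-6.65 ± 1.26) and Usp2 (-3.88 ± 0.67), a clock-controlled protease, fell. Outside the clock, Irs2 (3.61 ± 0.75, 1.87 without 50d replicate 2), an insulin receptor substrate, Loxl4 (3.72 ± 0.70) and Chrna4 (4.16 ± 0.72, 4.75 without 7d replicate 2 and 3.45 without 50d replicate 2) rose. Bnip3 (-1.43 ± 0.23), a mitophagy receptor, Por (-1.77 ± 0.37), the electron donor of cytochrome P450 enzymes, and Mfsd2a (-5.37 ± 0.93, -4.65 without 7d replicate 2 and -6.19 without 50d replicate 2) fell.

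Among the clock genes 3 of 15 rose, 5 fell and 7 did not pass (4 higher and 9 lower over the list alone, camera down at adjusted p = 0.000135, 0.275 if estimated). Among the cholesterol synthesis genes 0 of 23 passed with edgeR (15 higher over the list alone, 16 at an unadjusted p under 0.05, 6 by DESeq2, 7 by limma voom, camera up at adjusted p = 6.12e-18, 0.275 if estimated). Dhcr7 stood at 232 ± 7.14 against 91.5 ± 26.8 CPM and Hmgcs1 at 1028 ± 62.3 against 354 ± 63.4 CPM. Among the fatty acid oxidation genes 0 of 20 passed with edgeR (1 higher and 6 lower over the list alone, 9 at an unadjusted p under 0.05, 3 by DESeq2, 1 by limma voom, camera down at adjusted p = 7.39e-07, 0.533 if estimated). Cpt1a, which brings fatty acids into mitochondria, stood at 195 ± 47.4 against 418 ± 133 CPM. Among the neutrophil markers 0 of 9 passed with edgeR (7 lower over the list alone, 8 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma voom, camera down at adjusted p = 3.08e-05, 0.742 if estimated). Ltf stood at 9.96 ± 4.68 against 72.1 ± 92.9 CPM, where 7d replicate 3 held 228 CPM of the unscaled library and the other 7d libraries 13.6 to 33.2. Its log2 fold change of -2.85 did not pass and was -1.37 without that library, and camera gave the neutrophil markers an adjusted p of 0.0112 without it. Among the biliary and progenitor markers 0 of 15 passed with edgeR (1 higher over the list alone, 3 at an unadjusted p under 0.05, 1 by DESeq2, 1 by limma voom, camera up at adjusted p = 0.00605, 0.836 if estimated, 0.568 without 7d replicate 2, 0.0506 without 50d replicate 3). Among the acute phase genes 0 of 15 passed with edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom, camera up at adjusted p = 0.00398, 0.836 if estimated, 0.066 without 7d replicate 1). Among the glucose metabolism genes 0 of 12 passed with edgeR (4 lower over the list alone, 5 at an unadjusted p under 0.05, 3 by DESeq2, 1 by limma voom, camera down at adjusted p = 0.0266, 0.836 if estimated, 0.09 without 7d replicate 1, 0.344 without 7d replicate 2, 0.179 without 50d replicate 1, 0.125 without 50d replicate 3). Among the p53 targets 1 of 16 rose and 15 did not pass (2 higher over the list alone). The member that rose was Bbc3 (1.04 ± 0.20), an inducer of apoptosis. Mki67 stood at 12.3 ± 1.57 against 16.2 ± 12.9 CPM and Glul at 828 ± 53.2 against 813 ± 495 CPM.

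From 7d to 50d 60 of 13617 genes changed, 39 higher and 21 lower, and 1334 had an unadjusted p under 0.05. DESeq2 called 232, limma voom 122 and the fit with a replicate block 0, while the all-library fit called 19 and the fit of these groups alone 14. The count was 35 without 7d replicate 2, 21 without 50d replicate 1, 23 without 50d replicate 2 and 25 without 50d replicate 3. Of the 15 genes named here as changed, 11 did not pass without 1 library or more, and Arntl, Nfil3, Per3 and Tef passed in each case. The number lost was 1, 6, 3 and 5 without 7d replicates 1, 2, 3 and 4 and 9, 10 and 7 without 50d replicates 1, 2 and 3. The signs of median, mean and camera differed for fetal and tumor markers, Wnt and pericentral genes, interferon response genes, macrophage markers, sinusoidal endothelium markers, erythroid genes and corepressor and HDAC genes.

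**Figure D3:**
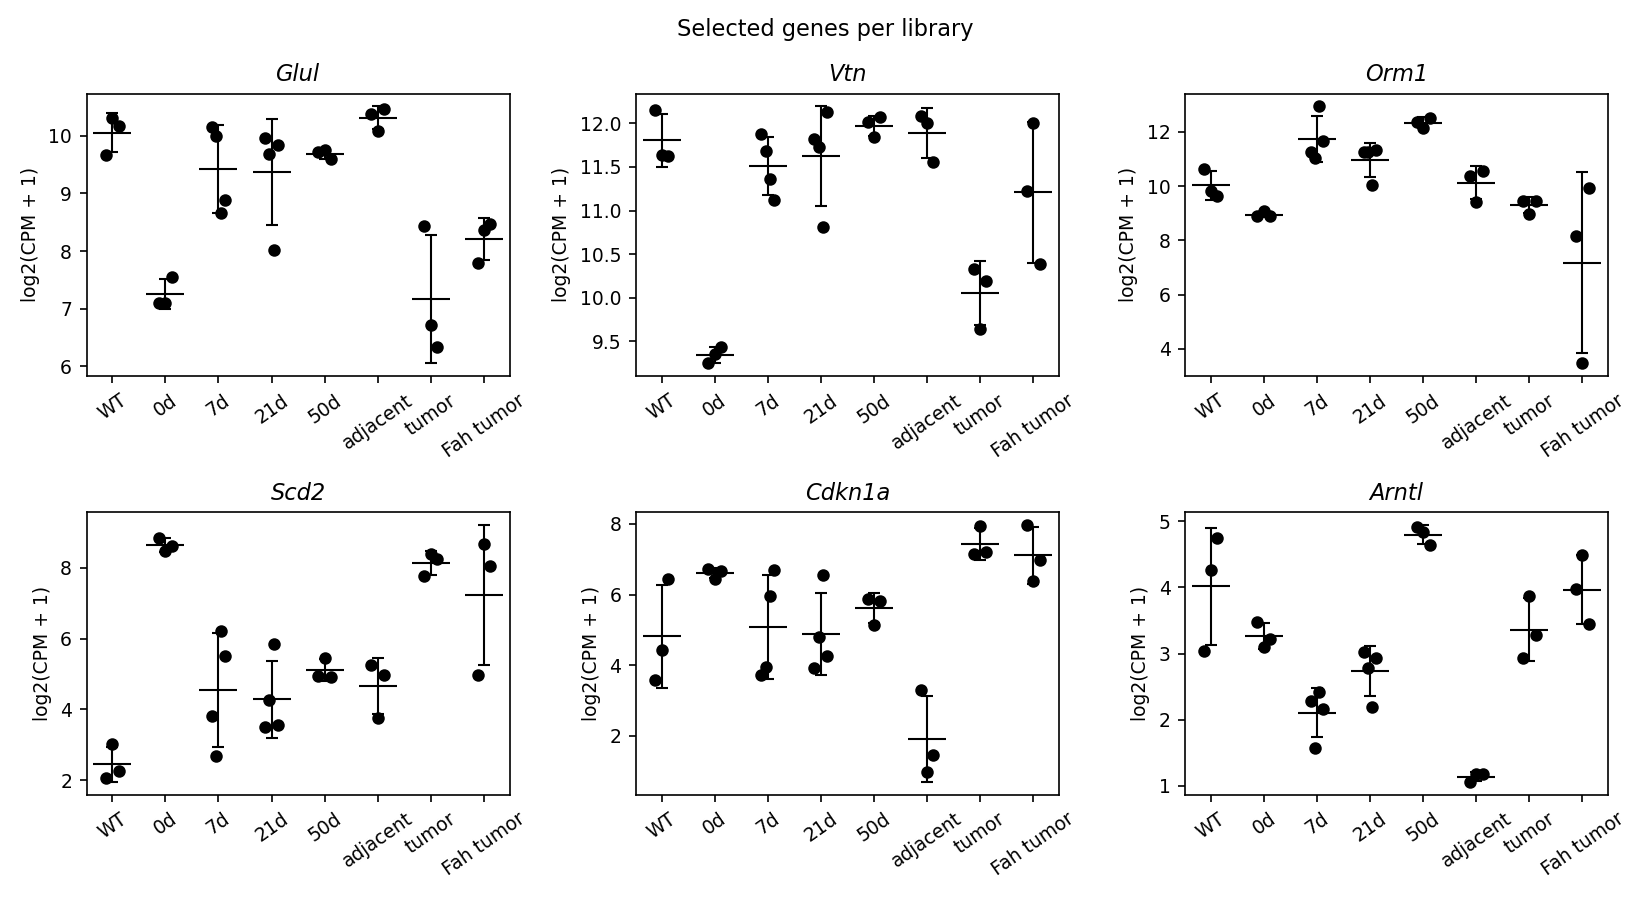
Levels of Glul, Vtn, Orm1, Scd2, Cdkn1a and Arntl as log2(CPM + 1), with 1 point per library, a bar at the mean ± SD and 8 groups on the horizontal axis. Glul and Vtn were lower in 0d than in WT and lower in Hdac3-/- tumors than in adjacent tissue.

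Tumors labelled Hdac3-/- held less of most pericentral and sterol genes and of some bile acid genes than adjacent tissue and more of many p53 targets and some cell cycle genes. Axin2 (-4.41 ± 0.51), Tbx3 (-5.26 ± 0.56, -6.01 without tumor replicate 1) and Nkd1 (-3.28 ± 0.43), targets of Wnt signalling, fell with Glul (162 ± 117 against 1397 ± 89.9 CPM, log2 fold change -3.11, -3.88 without tumor replicate 1) and Lect2 (-6.32 ± 0.72, -7.20 without tumor replicate 1). Cdkn1a (173 ± 67.7 against 3.94 ± 4.14 CPM, log2 fold change 5.44, 6.76 without adjacent replicate 1), the p21 cell cycle inhibitor, rose with Gdf15 (3.02 ± 0.28), Phlda3 (3.66 ± 0.40) and Btg2 (4.15 ± 0.47). The replication genes Mcm2 (2.68 ± 0.56, 1.97 without tumor replicate 1) and Mcm6 (3.58 ± 0.73, 2.52 without tumor replicate 1) and the mitotic kinase Cdk1 (3.09 ± 0.68) rose. Cyp7a1 (-6.42 ± 1.47, -7.33 without tumor replicate 1 and -5.51 without adjacent replicate 3) and Cyp8b1 (-7.00 ± 1.41, -9.16 without tumor replicate 1 and -6.37 without adjacent replicate 2), of bile acid synthesis, fell.

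Of the Wnt and pericentral genes 12 of 15 fell and 3 did not pass (14 lower over the list alone, camera down at adjusted p = 2.11e-13, 0.0336 if estimated). Of the p53 targets 10 of 16 rose and 6 did not pass (11 higher over the list alone, camera up at adjusted p = 4.79e-08, 0.0336 if estimated). Of the cell cycle genes 7 of 31 rose and 24 did not pass (18 higher and 1 lower over the list alone, camera up at adjusted p = 2.39e-06, 0.618 if estimated). Mki67 stood at 3.90 ± 2.51 against 0.954 ± 0.714 CPM (adjusted p = 0.197). Of the cholesterol synthesis genes 17 of 23 fell and 6 did not pass (21 lower over the list alone, camera down at adjusted p = 2.73e-12, 0.38 if estimated). Mvk (-2.89 ± 0.38) and Dhcr7 (-2.92 ± 0.56) fell. Of the bile acid genes 1 of 20 rose, 6 fell and 13 did not pass (1 higher and 13 lower over the list alone, camera down at adjusted p = 0.000463, 0.168 if estimated). Of the fetal and tumor markers 4 of 13 rose and 9 did not pass (5 higher over the list alone, camera up at adjusted p = 0.000785, 0.38 if estimated). Cbr3 (5.71 ± 0.80, 6.39 without adjacent replicate 1), Golm1 (3.38 ± 0.64) and Scd2 (3.31 ± 0.77) rose, while Afp stood at 20.2 ± 29.6 against 1.07 ± 0.355 CPM (adjusted p = 0.174). Of the biliary and progenitor markers 2 of 14 rose and 12 did not pass (4 higher and 1 lower over the list alone). These were Cd24a (3.47 ± 0.32) and Sox4 (3.89 ± 0.83, 5.48 without adjacent replicate 1), and Krt19 stood at 1.52 ± 0.0919 against 11.7 ± 6.89 CPM (adjusted p = 0.222). Of the lipogenesis and lipid droplet genes 3 of 25 rose and 22 did not pass (3 higher and 1 lower over the list alone). These were Plin2 (2.54 ± 0.41), Cidec (4.80 ± 0.89) and Fabp4 (4.96 ± 0.53, 5.63 without adjacent replicate 1), of lipid storage or transport. Of the hypoxia and glycolysis genes 3 of 15 rose and 12 did not pass (7 higher over the list alone, camera up at adjusted p = 0.00105, 0.478 if estimated). Pkm (3.09 ± 0.57, 2.50 without tumor replicate 2) and Hk2 (2.31 ± 0.55) rose. Of the xenobiotic enzymes 5 of 22 rose, 4 fell and 13 did not pass (7 higher and 8 lower over the list alone). Gsta1 (4.40 ± 0.42) rose and Cyp2c37 (-6.06 ± 0.57), of a family with near-identical copies, fell.

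Of the secreted plasma proteins 2 of 23 fell and 21 did not pass (2 lower over the list alone, camera down at adjusted p = 0.0058, 0.478 if estimated, 0.0526 without tumor replicate 1). Vtn (-2.03 ± 0.50) fell, and Alb stood at 56839 ± 35852 against 71057 ± 18257 CPM (adjusted p = 0.802). Of the urea cycle and amino acid genes 1 of 17 fell and 16 did not pass (1 lower over the list alone, camera down at adjusted p = 0.0394, 0.699 if estimated, 0.143 without tumor replicate 2, 0.132 without adjacent replicate 3). That member was Otc (-4.50 ± 1.14), a urea cycle enzyme. Of the interferon response genes 2 of 17 rose and 15 did not pass (2 higher over the list alone, camera up at adjusted p = 0.00409, 0.562 if estimated). Of the fatty acid oxidation genes 2 of 20 rose, 1 fell and 17 did not pass (2 higher and 1 lower over the list alone). Of the matrix and stellate cell genes 2 of 18 rose and 16 did not pass (3 higher over the list alone). These were Sparc (2.44 ± 0.55, 1.65 without tumor replicate 3) and Acta2 (3.11 ± 0.73, 2.43 without tumor replicate 2). Of the macrophage markers 1 of 16 rose, 1 fell and 14 did not pass (1 higher and 3 lower over the list alone). Cd14 (4.21 ± 0.85, 5.37 without adjacent replicate 1) rose and Clec4f (12.6 ± 13.5 against 101 ± 57.8 CPM, log2 fold change -3.00, -4.37 without tumor replicate 3), a marker of Kupffer cells, fell. Of the sinusoidal endothelium markers 1 of 11 rose and 10 did not pass (1 higher over the list alone). Of the acute phase genes 1 of 15 fell and 14 did not pass (4 at an unadjusted p under 0.05 and 0 over the list alone with edgeR, 3 by DESeq2, 3 by limma voom). Of the neutrophil markers 1 of 5 fell and 4 did not pass (1 lower over the list alone). Among the largest rises were Areg (7.63 ± 1.80, 6.28 without tumor replicate 1 and 9.60 without adjacent replicate 3), amphiregulin, Apln (7.58 ± 1.53, 6.70 without tumor replicate 2 and 9.58 without adjacent replicate 2), apelin, and Ptgs2 (7.37 ± 1.45, 9.34 without adjacent replicate 3), cyclooxygenase 2.

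Between tumor and adjacent tissue 1354 of 13187 genes changed, 697 higher and 657 lower. Without tumor replicates 1, 2 and 3 the counts were 644, 290 and 616, and without adjacent replicates 1, 2 and 3 they were 834, 485 and 487. Of the 37 genes named here as changed, 21 did not pass without 1 library or more, 10, 17 and 7 without tumor replicates 1, 2 and 3 and 12, 19 and 20 without adjacent replicates 1, 2 and 3. These were Mcm2, Mcm6, Cdk1, Cyp7a1, Cyp8b1, Dhcr7, Golm1, Scd2, Sox4, Cidec, Pkm, Hk2, Vtn, Otc, Sparc, Acta2, Cd14, Clec4f, Areg, Apln and Ptgs2. Without the libraries that held Y-linked transcripts, which leaves 2 of each kind, edgeR called 0 genes (2433 at an unadjusted p under 0.05), and no other tool was run on these. With these transcripts as a covariate it called 1047. Raet1d was at least 201-fold higher. Mup7, among the largest falls, belongs to a family of near-identical copies. Scaled by library totals, the median log2 fold change of all genes was 0.20 and 65.2% of the changed genes were higher, against 51.5%. The lipogenesis, macrophage and lymphocyte lists get no direction for that reason. The signs of median, mean and camera differed for biliary and progenitor markers, lipogenesis and lipid droplet genes and macrophage markers.

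Tumors of Fah-/- recipients and Hdac3-/- tumors gave no gene past edgeR's threshold, and wide differences in level did not pass. Afp was at 859 ± 1402 against 20.2 ± 29.6, Gpc3 at 218 ± 306 against 4.43 ± 3.60 and Krt19 at 36.7 ± 59.5 against 1.52 ± 0.0919 CPM in recipient and Hdac3-/- tumors. Glul was at 282 ± 39.1 against 162 ± 117 and Vtn at 2543 ± 1423 against 1039 ± 201 CPM. The matrix proteins decorin, Dcn, and lumican, Lum, were at 10.7 ± 9.18 against 64.7 ± 13.9 and 1.20 ± 1.44 against 9.69 ± 3.97 CPM. Among the matrix and stellate cell genes 0 of 18 passed with edgeR (2 lower over the list alone, 3 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma voom, camera down at adjusted p = 3.68e-07, 0.963 if estimated). Among the cell cycle genes 0 of 31 passed with edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom, camera up at adjusted p = 2.53e-05, 0.963 if estimated, 0.0799 without tumor replicate 3, 0.204 without recipient tumor replicate 3). Among the fetal and tumor markers 0 of 13 passed with edgeR (4 higher and 1 lower over the list alone, 5 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma voom). Among the Wnt and pericentral genes 0 of 15 passed with edgeR (2 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom). Among the p53 targets 0 of 16 passed with edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom). Of 13187 genes 0 passed with edgeR, 912 had an unadjusted p under 0.05, and DESeq2 called 42 and limma voom 0. The fit of all 26 libraries called 76, and edgeR called 1 without recipient tumor replicate 3. In counts simulated for this comparison, with 12991 genes tested, edgeR recovered 35% of 4-fold and 1% of 2-fold changes. Median, mean and camera disagreed in sign for fetal and tumor markers, lipogenesis and lipid droplet genes, glucose metabolism genes, Wnt and pericentral genes, p53 targets, acute phase genes and erythroid genes.

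The design text names a Pearson correlation of both kinds of tumor. Across 19638 genes, on log2(FPKM + 1), the 9 pairs of Hdac3-/- and recipient tumors correlated at 0.951 ± 0.025 (mean ± SD, range 0.913 to 0.989). Pairs within Hdac3-/- tumors correlated at 0.973 ± 0.00806 and pairs within recipient tumors at 0.933 ± 0.0198 (3 pairs each). Hdac3-/- tumors correlated with adjacent tissue at 0.917 ± 0.0128, with WT at 0.915 ± 0.00433 and with 0d at 0.959 ± 0.00159 (9 pairs each). Recipient tumors correlated with adjacent tissue at 0.892 ± 0.0269, with WT at 0.882 ± 0.027 and with 0d at 0.931 ± 0.0259. The mean within tumor groups exceeded the mean between them by 0.00204 (one-sided exact permutation p = 0.5, with 10 splits that allow no p below 0.1). Genes are not independent replicates, and genes high in every liver sample raise each of these values.

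Changes in young livers and in tumors were set side by side in 12944 genes. Across genes, the log2 fold changes of tumor against adjacent tissue correlated at 0.67 with those of 0d against WT, at -0.56 with those of 7d against 0d and at -0.55 with those of 50d against 0d. Genes higher in 0d than WT and in tumor numbered 514 (122.4 by chance), and genes lower in both 474 (127.5). Glul, Lect2, Dhcr7 and Vtn were lower in both, and Cd24a, Sox4, Golm1 and Btg2 were higher in both. Opposite calls numbered 7 and 6 (119.5 and 130.6 by chance). Genes higher at 50d and lower in tumor numbered 388 (95.3 by chance) and the reverse 297 (77.4), against 8 and 11 in the same direction (97.6 and 75.5). For 7d the opposite calls were 398 and 275 (97.0 and 80.3 by chance), and those in the same direction 2 and 7 (99.3 and 78.4). Counts by chance are those of independent lists. All of these comparisons of young livers use the same 0d libraries, so their correlations and overlaps with tumor changes are not independent of one another.

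Many genes that differed between WT and 0d moved the other way at the later days. Of the genes higher in 0d than WT, 1030 were lower at 7d, 1194 at 21d and 1008 at 50d than at 0d (296.6, 349.1 and 283.8 for independent lists). Of those lower in 0d, 1433, 1632 and 1348 were higher at these days (381.5, 455.7 and 372.1). Across 13617 genes the fold changes correlated at -0.63, -0.70 and -0.64. In 10 simulations of unchanged groups sharing a 0d group, correlations were -0.53, -0.53 and -0.50 with 0 opposite calls. The covariances were -0.85, -0.96 and -0.94, against -0.08 in each simulated set. The 3 libraries of 0d are too few to split, so part of the excess over independent lists may come from sharing them. On a scale with WT at 0 and 0d at 1, over 4260 genes that differed between them, 7d libraries lay at 0.26, 0.12, 0.65 and 0.69. The 21d libraries lay at 0.24, 0.35, 0.64 and 0.25 and the 50d libraries at 0.39, 0.41 and 0.37. Hdac3-/- tumors lay at 0.86, 0.89 and 0.82, adjacent tissue at 0.23, 0.05 and 0.10 and recipient tumors at 0.89, 0.88 and 0.88.

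**Figure D4:**
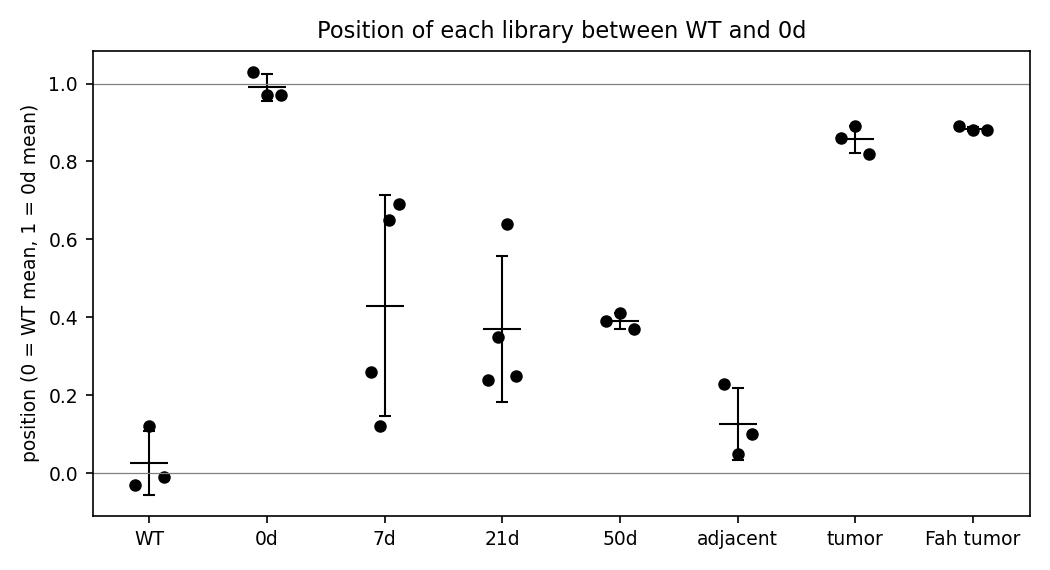
Position of each library between the mean of WT (0) and of 0d (1) over 4260 genes that differed between these groups, with 1 point per library, bars at the mean ± SD and 8 groups on the horizontal axis. Tumors of both kinds lay near 0d, adjacent tissue at 0.05 to 0.23 and the libraries after sPH at 0.12 to 0.69.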

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

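All tests of explanations here except the one of library size were chosen only after the result was seen, as were the counts of other splits.

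Between 50d and 7d livers, time points of the same contrast with 0d, 60 genes differed by a direct test. In the 2 groups of 4 libraries, 12 of 103 sets of values had 1 library far from the other 3, where chance gives about 1 in 20. In 7d replicate 3, Saa1 (15049 CPM of the unscaled library, as are all levels in this paragraph), S100a9 (616), Ltf (228) and Marco (637) lay above the other 7d libraries. Mup1 was high in 7d replicate 2 (1371), Por was low in 7d replicate 1 (428), and Hbb-bs and Hbb-bt made up 48.1% of adult beta-globin counts in 7d replicate 4. In 21d replicate 3, H19 (359), Igf2 (11.3), Ccnd1 (83.6) and Scd1 (11273) lay above the other 21d libraries and Apcs (348) below them.

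The first pattern weighed was the change of many genes from 0d to the later days, which also separated livers without from livers with Y-linked transcripts. Among the genes called at 7d, 21d and 50d, the difference between older libraries with and without these transcripts, signed by the call, had medians of 0.12, 0.15 and 0.10 (log2), against median changes of 0.98, 0.97 and 1.08 and SDs over genes of 0.55, 0.50 and 0.53. The medians lie below the changes by more than these SDs, which are spreads over genes and not errors of the medians. Of the called genes 62.7, 66.4 and 60.7% had the same sign. These values rest on 1 library with Y-linked transcripts in each of tumor and adjacent tissue, so they decide nothing. A fixed difference between the sexes cannot be told apart from the days after sPH. Nor can a sex difference of young Hdac3-/- livers, since 0 libraries after sPH lacked Y-linked transcripts. Regeneration after sPH, the difference the design names, stays open and untested for the same reason. Hbb-bs and Hbb-bt made up 52.7 to 99.6% of adult beta-globin counts in 0d and at most 48.1% in the later libraries. A difference in strain background therefore cannot be told apart from the days after sPH either.

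The second pattern was the spread of libraries after sPH between the levels of WT and 0d, with 7d libraries over a range of 0.57 of that distance. RNA from livers without Y-linked transcripts would need Xist at 153.4 CPM in the farthest library, and the highest 7d value was 4.29, which argues against it. Thinning all libraries to the same total moved no position by over 0.0012 and left the range at 0.57. As thinning hardly moved any position, it cannot decide whether unequal totals caused the spread. Other differences between libraries that go with their totals were not tested. Of the 4 smallest libraries after sPH, 7d replicates 4 and 3 (8602526 and 9195169 counts) and 21d replicate 3 (8993223) lay nearest to 0d, at 0.69, 0.65 and 0.64, while 21d replicate 4 (9192544) lay at 0.25. Over 11 libraries a higher Hdac3 level went with a position nearer to 0d, whose mean Hdac3 level was also above that of WT (Pearson r = 0.80, permutation p = 0.00339, Spearman rho = 0.73, permutation p = 0.0149, 100000 resamples, r = 0.73 without the 2 farthest libraries). Hdac3 levels and positions were both scaled by library totals, with which the median log2 fold change of all genes was 0.30 in 0d against WT. Part of the relation may come from that scaling. As 17.3% of 13617 genes followed the position as closely, the relation to Hdac3 stays open, and no biological explanation of the spread within a day was tested.

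The third pattern was the change of clock genes between 7d and 50d. Of 15 clock genes 8 passed the test and 7 did not, among them Cry1 (log2 fold change 0.086, adjusted p = 0.975). The fitted changes of 15 of 15 had the sign of their known phase, where the phases were set after the changes were seen. A difference in the time of day of collection may give this, but it cannot be told apart from a lasting effect of the days after sPH on the clock, since the labels give no time of collection.

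Other splits of the same libraries gave these counts. For 7d and 21d against 0d, only the real split of 35 gave as many genes (3626 and 4303, highest other 2760 and 4068). Over 7 comparisons this does not exclude chance. For 50d against 7d, 2 of 35 splits gave as many, and another split called 702 genes against 60, which points to a structure of the samples, so chance is not excluded. For 0d against WT, 50d against 0d and tumor against adjacent, 10 splits each are too few for a share under 0.05 (real 5082, 3507 and 1354, highest other 3, 0 and 0). The same holds for recipient against Hdac3-/- tumors (real 0, highest other 7, with 10 of 10 splits at least as high).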

How the results depend on the processing

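Apart from the settings on Y-linked transcripts and camera with 1 library left out, the settings here were chosen before the data were examined. Of 260 counts and summary values under other settings 190 stayed within the spread or 1.5 times the main value, 35 counts of changed genes were lower and 13 higher by more than that, and 22 other values moved by more. None of the correlations changed sign but the difference of correlations within and between tumor groups, near 0, when Hdac3-/- tumor replicate 1, 2 or 3 was left out. Of 20092 values of named genes and gene lists 18290 kept their side of the threshold, 471 passed it, 1330 no longer did and 1 was reversed. That was the lipogenesis list between the tumors, which camera called up without recipient tumor replicate 2, down without replicate 1 and not with all libraries (down), with an adjusted p of 0.0121 to 0.847 when 1 library was left out. Replicate numbers showed no pairing, so the replicate block stands here as an alternative only. Where not said, the cause was not tested.

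With a 2-fold minimum, a stricter rule by construction, 3070 genes changed in 0d against WT, 1764 at 7d, 2054 at 21d and 1949 at 50d against 0d. At an adjusted p of 0.01 the counts were 2901, 1522, 2109 and 1585, with 21 in 50d against 7d and 253 in tumor against adjacent. In a fit of all 26 samples they were 2103 at 7d, 2804 at 21d and 2078 at 50d against 0d, 19 in 50d against 7d, 3936 in tumor against adjacent and 76 between the tumors. With only the groups compared they were 5697 at 50d against 0d, 14 in 50d against 7d and 2437 in tumor against adjacent. The replicate block gave 1901 at 7d and 5340 at 50d against 0d and 0 in 50d against 7d. Limma voom gave 7657 at 21d and 7290 at 50d against 0d, 122 in 50d against 7d and 2755 in tumor against adjacent. DESeq2 gave 232, 2392 and 42 in 50d against 7d, tumor against adjacent and between the tumors. Without libraries holding Y-linked transcripts, which leaves fewer samples, edgeR called 0 genes in tumor against adjacent (2433 at an unadjusted p under 0.05).

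The balance of higher and lower genes turned under some settings. Of the genes changed at 7d, 21d and 50d against 0d, 55.3, 55.6 and 55.7% were higher, against 38.0, 35.1 and 39.2% with library totals. With limma-trend on log2(FPKM + 1) they were 31.0, 31.8 and 34.7%, and on log2(FPKM + 0.1) 34.0, 34.4 and 39.0%. The replicate block gave 43.1% at 7d and 48.9% at 50d, and the groups compared alone 49.9% at 50d. In 0d against WT 49.0% were higher, against 69.7% with library totals, 71.7 and 70.9% with limma-trend, 54.6% with a 2-fold minimum and 51.2% with the replicate block. In tumor against adjacent 51.5% were higher, against 48.6% with limma voom and 46.9, 48.2 and 48.9% without adjacent replicates 1, 2 and 3. No gene changed in both the main and another setting had opposite signs in them.

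Camera with an estimated correlation called 2 lists in tumor against adjacent and 0 otherwise. Fry called 7 there, 17 in 0d against WT, 17, 15 and 14 at 7d, 21d and 50d against 0d and 0 otherwise. The mean correlation of the tumors was 0.915 over genes with a mean FPKM of at least 1, and Spearman's correlation of 50d and tumor changes was -0.48.

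Leaving out 1 library at a time gave 3752 to 4871 genes in 0d against WT, 1752 to 4134 at 7d, 2484 to 5116 at 21d and 1995 to 3463 at 50d against 0d. It gave 21 to 78 in 50d against 7d, 290 to 834 in tumor against adjacent and 0 to 1 between the tumors. Camera then called 16 to 18 lists in 0d against WT, 16 to 20 at 7d, 18 at 21d and 14 to 18 at 50d against 0d, 5 to 12 in 50d against 7d, 10 to 13 in tumor against adjacent and 1 to 8 between the tumors. The mean correlation of the tumors ran from 0.939 to 0.966, and within minus between from -0.0103 to 0.0197. Correlations with tumor changes ran from -0.56 to -0.49 for 50d, from -0.61 to -0.48 for 7d and from 0.62 to 0.68 for 0d against WT. In the simulated counts 15 and 35% of 4-fold changes were recovered in the tumor comparisons and 78 to 87% in those of young livers.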

Other observations

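Some immediate early genes, which respond within minutes to stress and handling, were higher in 0d livers than WT, and some in tumors than in adjacent tissue. In 0d against WT 8 of 13 rose, 2 fell and 3 did not pass (8 higher and 2 lower over the list alone, camera up at adjusted p = 0.018, 0.548 if estimated, 0.0574 without WT replicate 3). Atf3 (4.12 ± 0.74) and Jun (1.98 ± 0.38), transcription factors of the stress response, and Ier3 (2.50 ± 0.53) rose. In tumor against adjacent tissue 5 of 13 rose and 8 did not pass (8 higher over the list alone, camera up at adjusted p = 0.000573, 0.38 if estimated). Ier3 (2.94 ± 0.47, 3.54 without adjacent replicate 1), Klf6 (2.37 ± 0.46), Atf3 (3.23 ± 0.64) and Junb (1.37 ± 0.32) rose. Klf6 did not pass without tumor replicate 2 or adjacent replicate 3, Atf3 without these or adjacent replicate 2, and Junb without any 1 of the tumor libraries or of adjacent replicates 1 and 3. In 7d against 0d 4 of 13 rose and 9 did not pass (4 higher over the list alone).

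Most corepressor and HDAC genes, which include parts of the complex in which Hdac3 acts, did not pass the test in 0d against WT, at 7d or in tumors, and 6 of 11 did not at 21d and at 50d. Of these genes 2 of 11 rose and 9 did not pass (2 higher over the list alone) in 0d against WT. Tbl1x (2.28 ± 0.55, 2.92 without WT replicate 2) and Tbl1xr1 (0.67 ± 0.20), subunits of the NCoR corepressor complex, rose. At 7d against 0d 1 of 11 rose, 1 fell and 9 did not pass (1 higher and 3 lower over the list alone). Tbl1x (-2.54 ± 0.50) fell and Hdac1 (0.55 ± 0.14) rose at 7d. At 21d against 0d 1 of 11 rose, 4 fell and 6 did not pass (2 higher and 4 lower over the list alone) and at 50d against 0d 1 of 11 rose, 4 fell and 6 did not pass (1 higher and 4 lower over the list alone). In tumor against adjacent tissue 1 of 11 rose and 10 did not pass (1 higher over the list alone). Tbl1xr1 (0.94 ± 0.20) rose in tumors. It did not pass in tumors without any 1 of the 6 libraries, nor in 0d livers without WT replicate 1 or 0d replicate 1 or 2. Lymphocyte markers went both ways in 0d livers, where the granzymes Gzma (-3.31 ± 0.85, -2.45 without WT replicate 2) and Gzmb (-2.94 ± 0.90, -1.23 without WT replicate 2) of killer cells fell while Ptprc (1.38 ± 0.38), of leukocytes, and Cd79a (1.21 ± 0.38), of B cells, rose. Gzmb did not pass without WT replicate 2 or 0d replicate 3, nor Cd79a without WT replicate 1 or 0d replicate 2 or 3. Among the clock genes 4 of 15 rose, 2 fell and 9 did not pass (4 higher and 5 lower over the list alone) in tumor against adjacent tissue. Arntl (2.82 ± 0.47) and Nfil3 (1.21 ± 0.28) rose and Per3 (-3.62 ± 0.47) and Tef (-1.63 ± 0.32) fell. Nfil3 did not pass without tumor replicate 1 or 2 or adjacent replicate 1 or 3, nor Tef without tumor replicate 1 or 2 or adjacent replicate 2. Of the exocrine pancreas genes 0 of 2 passed with edgeR (1 at an unadjusted p under 0.05, 1 by DESeq2, 1 by limma voom) in 0d against WT.

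Further pairs of days were compared with edgeR only. Between 21d and 50d 60 genes changed, 36 higher and 24 lower at 50d, and 1646 had an unadjusted p under 0.05. Between 7d and 21d 0 genes passed with edgeR, and 1051 had an unadjusted p under 0.05. These pairs were added after the data were seen.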
